A study of Mus musculus with 9 samples.

How the data were processed

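RNA was measured in whole liver of male mice aged 8 to 9 weeks with 9 single-channel Affymetrix gene arrays, 1 per mouse as far as the labels tell. Per the labels' protocols, labelled cDNA was made from total RNA without removal of ribosomal RNA, and only RNA without signs of degradation was hybridised. The labels give 3 groups of 3: wild type, a knockout of NEMO restricted to hepatocytes, and a cross of that knockout with mice constitutively lacking p21, called the labelled double knockout throughout because its Cdkn1a signal was not reduced. There was no group lacking p21 alone. P-values therefore measure the spread between these samples, which the labels describe as separate animals only through different identifiers.

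The deposited table holds log2 expression values, 1 per probe set and array, and the submitters' processing notes name RMA (background correction, quantile normalisation and median polish of the probes of a set). The log base is not written in the table and was taken from RMA and from the range of the values. Software versions, the genome build and any filter are not given in the sources used here. RMA's quantile step pulls the arrays toward 1 common distribution, so a general rise or fall of all RNA would not be seen, and its median polish can give several arrays the very same value. Of the probe sets tested, 1203 (4.16%) had 1 repeated value on all arrays of some group, 2 of them on all 9 arrays. These stayed in the tests, where they made 7, 0 and 15 of the calls in the 3 comparisons taken in the order of the report. No pair of arrays was identical. The arrays give no read depth, and their small number limits the precision.

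From these values the following was computed. The table has 35556 probe sets. A block of 6617 (18.6%) with identifiers below the first one in the platform annotation, none of them annotated, was taken to be control probe sets and left out, which is an inference from the identifiers. The remaining 28939 were tested. The platform annotation gave 1 gene symbol to 21789 of them, several to 1621 and none to 5529. Of the single-symbol probe sets, 21698 matched the NCBI gene table of assembly GRCm38.p6 by gene identifier and 91 did not. Genes were named only from probe sets with 1 symbol, except that the single Cdkn1a probe set, which is annotated to 4930567H12Rik as well, is reported as such, and that calls with Rps2 in a joint annotation are counted. The gene table was used only for names and for which genes lie near each other. Members of gene families with near-identical sequence, such as histone, major urinary protein, Cyp2c, Clca3a and Rps2 probe sets, can share signal and are uncertain.

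Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) on all 9 arrays with 1 mean per group, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested. A probe set was called at an adjusted p under 0.05. Differences are given on the log2 scale as mean difference ± standard error (SE), with 3 arrays per group. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, 2-sided, using for each gene the probe set with the highest mean, and adjusted over the 33 lists that had at least 5 measured genes. The 34 lists held 556 genes, of which 502 were measured. Beside it stand camera with an estimated inter-gene correlation and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes. Counts of called members use the adjustment over all probe sets and, in a second value, an adjustment over the list alone. Comparisons that share arrays were set against 100 simulations of unchanged groups on the same design, and the share of calls within 10 Mb of Cdkn1a against all other genes by Fisher's exact test, 2-sided.

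On simulated data with 200 changed probe sets among 28939, the fit of the NEMO knockout against wild type recovered 43 of 67 changes of 0.5, 64 of 67 changes of 1 and 66 of 66 changes of 2 on the log2 scale, with 8 false calls. For the labelled double knockout against the NEMO knockout the numbers were 43 of 67, 67 of 67 and 66 of 66, with 11 false calls. The simulated noise was normal, independent between probe sets and of the spread moderated by limma, so these numbers need not hold for the real data. Ly6d, at -2.57 (SE 0.64) in that real comparison, was not called.

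Most of the named genes follow a rule. For each of the first 2 comparisons they are Ikbkg and Cdkn1a, the 10 largest increases and the 10 largest decreases among called probe sets with 1 symbol whose groups did not overlap (predicted genes without a given name, olfactory and vomeronasal receptors and small RNAs passed over), and up to 4 called members of each list with the largest change. For the third comparison the rule takes the 5 largest changes each way and the list members already named. Cyp7a1, Cdk1, Top2a, Cxcl9, Il1rn, Crp, Cd5l, Per3, Sult1e1, Pgap6, Arhgef40, Cebpe and G2e3 fall outside it and were chosen after their values were seen. The groups, lists, tests, this rule and most alternatives were fixed before the data were examined. The alternatives were other normalisations between arrays, a filter on dim probe sets, other variance models, array weights, fits on 2 groups, a block for the replicate number, each array left out in turn, other thresholds and other list tests. Leaving out tied probe sets or those of Rps2, including the control block, counting genes near Cdkn1a by any of their probe sets, counting calls that lie close together, and leaving out the first array of both knockout groups were chosen after seeing the data. The count of calls within 5 Mb of another call was made after their positions had been looked at. It leaves out members of the cell cycle, DNA damage and p53 lists, histone genes and pairs closer than 100 kb. Genes of dividing cells outside these lists stayed in. The count was set against 10000 random gene sets. It first served as the test of DNA from another strain, and the test near Cdkn1a took that place after both values were known. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.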

Results

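Liver RNA profiles of 3 genotypes were compared to ask what changes when hepatocytes lose NEMO, and what changes further when p21 is lost as well. NEMO, encoded by Ikbkg, is the regulatory subunit of the IκB kinase complex that activates NF-κB. The p21 protein, encoded by Cdkn1a, inhibits cyclin-dependent kinases and is a transcriptional target of p53. Each group had 3 arrays from male mice aged 8 to 9 weeks. The array medians lay between 6.47 and 6.58 (log2). Across probe sets, which are not independent replicates, arrays correlated at r = 0.994 to 0.996 within groups and 0.986 to 0.995 between groups. The first principal component held 46.7% of the variance and placed all 3 wild type arrays on one side and all 6 knockout arrays on the other. On the second component (14.7%) NEMO knockout replicate 1 (6.28) stood apart from replicates 2 and 3 of its group (-17.1 and -22.9) and within the range of the labelled double knockout (3.18 to 23.6). NEMO knockout replicate 1 also had the lowest array weight, 0.412. Replicate 1 had the highest second component value of its group in wild type (3.745) and the labelled double knockout (23.57) as well.

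The targeted genes were examined first. Ikbkg was lower in the NEMO knockout (8.35 ± 0.13 log2, SD, n = 3) than in wild type (8.87 ± 0.13), a difference of -0.52 ± 0.11 (SE; limma adjusted p = 0.0184). The labelled double knockout had 8.27 ± 0.18, which was -0.60 ± 0.11 from wild type (adjusted p = 0.00835) and -0.08 ± 0.11 from the NEMO knockout (adjusted p = 0.928). Whole liver also holds cells in which NEMO was left intact. The Ikbkg call against wild type in the NEMO knockout ended when wild type replicate 2 or 3 or NEMO knockout replicate 1 or 3 was left out (adjusted p = 0.0625, 0.0729, 0.0524 and 0.0647). Its differences ran from -0.59 to -0.46 with each array left out in turn. Without labelled double knockout replicate 1 the difference between the knockout groups was 0.01 instead of -0.08.

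The single probe set annotated to Cdkn1a, jointly with 4930567H12Rik, went against the label. It read 8.67 ± 0.91 in wild type, 10.10 ± 0.53 in the NEMO knockout and 10.78 ± 0.56 in the labelled double knockout (log2, SD, n = 3). The labelled double knockout was 2.11 ± 0.45 above wild type (adjusted p = 0.0194) and 0.68 ± 0.45 above the NEMO knockout (adjusted p = 0.803), and the NEMO knockout was 1.43 ± 0.45 above wild type (adjusted p = 0.101). Where the probes lie relative to the deleted part of the gene was not analysed here, so this signal does not test the loss of p21 protein, and every direction given below for the labelled double knockout rests on its label. The call against wild type ended without wild type replicate 1 or 3 or labelled double knockout replicate 1 or 3 (adjusted p = 0.0633, 0.062, 0.0706 and 0.0764) and with only the 2 groups in the fit (0.0507). The NEMO knockout difference passed the threshold without wild type replicate 2 (1.91, adjusted p = 0.0283) and with array weights (1.69, adjusted p = 0.0479).

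**Figure D1:**
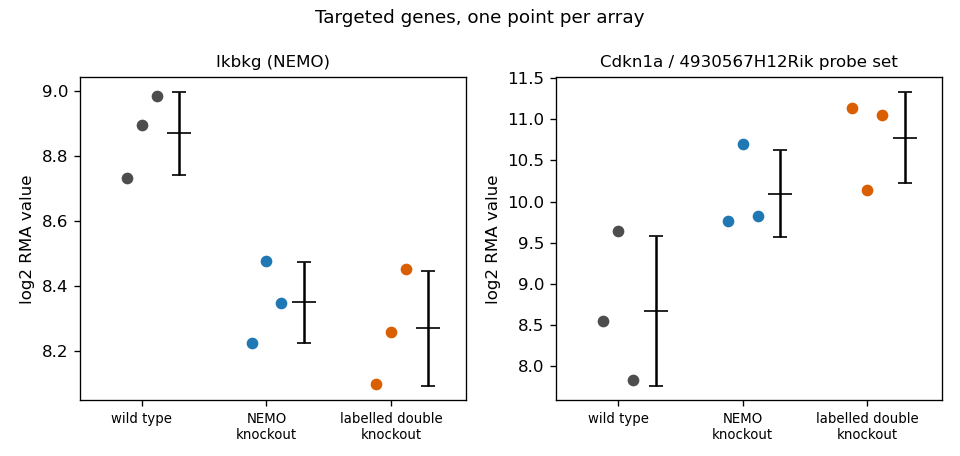
Log2 RMA values of the Ikbkg probe set (left) and of the probe set annotated to Cdkn1a and 4930567H12Rik (right), 1 point per array, with the group mean and SD as a bar beside the points; the vertical axes do not start at 0. Every knockout array read lower for Ikbkg than the wild type arrays, while the Cdkn1a probe set averaged 8.67, 10.10 and 10.78 in wild type, NEMO knockout and labelled double knockout.

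With the values as deposited, livers lacking NEMO in hepatocytes had more probe sets called higher (1638) than lower (584) relative to wild type, a share of 73.7% that was 52.7% (1304 and 1169) with each array centred on its median. The largest increases were in Ly6d, a surface protein of the Ly6 family (4.55 ± 0.64, 23.5-fold, adjusted p = 0.00272), Gpnmb, a glycoprotein of lipid-laden macrophages (3.56 ± 0.15, 11.8-fold, adjusted p = 2.93e-05), and Mmp12, the macrophage elastase (3.51 ± 0.28, 11.4-fold, adjusted p = 0.00025). Hsd3b5, a male-biased steroid dehydrogenase, had the largest decrease (-4.57 ± 0.51, 23.7-fold, adjusted p = 0.000962). The lists for extracellular matrix, infiltrating macrophages and mitosis passed upward, with 15 of 19, 10 of 14 and 18 of 26 genes called higher, and those for bile acid synthesis and male-biased genes downward, with 4 of 12 and 3 of 10 called lower. The calls for mitosis, bile acid synthesis and male-biased genes were lost at adjusted p = 0.141, 0.0825 and 0.0708 with an estimated correlation. In all, 2222 of 28939 probe sets were called, of which 383 were raised and 36 lowered at least 2-fold. At an unadjusted p under 0.05 there were 5881, against 1447 by chance.

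Next were the increases of the transcript D17H6S56E-5 (3.28 ± 0.37), Sprr1a, a small proline-rich protein of the cornified envelope (3.26 ± 0.53), Gldn (2.82 ± 0.39) and the transcription factor Mybl1 (2.82 ± 0.33). They were followed by the steroid-metabolising enzyme Akr1c18 (2.56 ± 0.45), Nipal2 (2.53 ± 0.22) and the collagen-binding proteoglycan Lum (2.50 ± 0.16). The decreases below Hsd3b5 were in the pseudogene Serpina4-ps1 (-3.01 ± 0.55), the receptor Adgrf1 (-2.42 ± 0.27), the fatty acid elongase Elovl3 (-2.39 ± 0.39), the oxysterol hydroxylase Cyp7b1 (-1.99 ± 0.33), the haemoglobin scavenger receptor Cd163 (-1.85 ± 0.20) and Mup21 (-1.85 ± 0.31). Cyp2c37 (-1.69 ± 0.22), the heat shock protein Hsph1 (-1.50 ± 0.38) and the chemokine Cxcl13 (-1.40 ± 0.26) completed the 10. The adjusted p-values of these genes lay under 0.05, with Hsph1 nearest to it at 0.0431. Without NEMO knockout replicate 3 the number of calls was 1382. Centring the arrays moved the median difference of all probe sets from -0.04 to -0.10.

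Of the 33 lists tested, 25 passed camera, 20 upward and 5 downward. Those for extracellular matrix and fibrosis, monocytes and infiltrating macrophages, and p53 targets held with an estimated correlation. In the extracellular matrix list 15 of 19 measured genes rose, none fell and 4 did not pass (17 higher when adjusted over the list alone; median 1.37; camera adjusted p = 1.38e-20; adjusted p = 0.0333 with an estimated correlation). Its examples besides Lum are the collagenase Mmp13 (2.13 ± 0.29), the gelatinase Mmp2 (1.99 ± 0.21) and the protease inhibitor Timp1 (1.77 ± 0.21). Markers of stellate cells, which make matrix, moved with it: 6 of 12 rose, Pdgfra by 1.55 ± 0.19, Cygb by 1.38 ± 0.10 and Pdgfrb by 1.36 ± 0.14. Of the 12, 1 fell (8 higher and 1 lower when adjusted over the list alone; camera adjusted p = 1.08e-06). That call was lost at adjusted p = 0.105 with an estimated correlation.

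Marker lists of some leukocytes passed upward alongside the matrix genes, and that of B cells did not (camera adjusted p = 0.126, none of 9 called). Among monocyte and infiltrating macrophage markers 10 of 14 rose and none fell (11 when adjusted over the list alone; median 1.06; camera adjusted p = 5.24e-15; adjusted p = 0.0333 with an estimated correlation). Besides Gpnmb and Mmp12, Itgax rose by 1.62 ± 0.17 and the chemokine receptor Ccr2 by 1.26 ± 0.15. In the Kupffer cell list 7 of 12 genes rose, such as Adgre1 (0.99 ± 0.13) and C1qb (0.95 ± 0.07), and Cd163 fell (8 and 1 when adjusted over the list alone; camera adjusted p = 2.88e-07; adjusted p = 0.0825 with an estimated correlation). For neutrophils 2 of 12 markers rose, Retnlg by 0.76 ± 0.18 and Csf3r by 0.68 ± 0.09 (4 when adjusted over the list alone; camera adjusted p = 0.000568; adjusted p = 0.17 with an estimated correlation). T and NK cell markers had 3 of 13 higher, Cd3g by 0.91 ± 0.18, Nkg7 by 0.73 ± 0.17 and Ncr1 by 0.73 ± 0.13 (4 when adjusted over the list alone; camera adjusted p = 0.00128; adjusted p = 0.184 with an estimated correlation). Cholangiocyte and ductular markers had 5 of 12 higher, including Cd24a (1.56 ± 0.28) and Epcam (0.74 ± 0.17), and 6 when adjusted over the list alone (camera adjusted p = 9.51e-05; adjusted p = 0.153 with an estimated correlation). Lists for B cells, endothelial cells, adipocytes and exocrine pancreas did not pass, and none of their members was called.

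The mitosis list had most of its members called in the NEMO knockout, while in the other cell cycle lists most did not pass. In the mitosis list 18 of 26 genes were higher and none lower (24 when adjusted over the list alone; median 0.94; camera adjusted p = 3.23e-18; adjusted p = 0.141 with an estimated correlation). Among them were the cyclins Ccnb2 (2.33 ± 0.36) and Ccna2 (2.11 ± 0.39), the proliferation marker Mki67 (1.92 ± 0.32) and the kinesin Kif20a (1.82 ± 0.24). DNA replication genes had 5 of 25 higher, such as the ribonucleotide reductase subunit Rrm2 (1.11 ± 0.23) and the helicase subunit Mcm6 (1.10 ± 0.26). Mcm10 fell by 0.67 on the log2 scale (11 and 1 when adjusted over the list alone; camera adjusted p = 4.74e-06; adjusted p = 0.265 with an estimated correlation). Cyclin D1, Ccnd1, rose 3.99-fold (adjusted p = 0.000881) and the kinase inhibitor Cdkn2c by 1.01 ± 0.13. They are 2 of the 4 genes called among 18 regulators of the first cell cycle phase, such as cyclins, kinases and kinase inhibitors (5 when adjusted over the list alone; camera adjusted p = 0.00153; adjusted p = 0.0708 with an estimated correlation). Of 23 p53 targets 10 rose and none fell (14 when adjusted over the list alone; median 0.38; camera adjusted p = 5.29e-09; adjusted p = 0.0333 with an estimated correlation). The largest increases were those of the receptor Eda2r (1.69 ± 0.10), Ckap2 (1.54 ± 0.27), Btg2 (1.29 ± 0.33) and Phlda3 (1.21 ± 0.10). Ckap2 is also a spindle protein. Rad18 (0.80 ± 0.10) and Chek2 (0.63 ± 0.10) were the 2 genes called among 23 of DNA damage response and repair, also when adjusted over the list alone (camera adjusted p = 0.00153; adjusted p = 0.26 with an estimated correlation).

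Interferon, cell death and NF-κB lists passed upward with fewer than 50% of their members called higher, and none of the 3 held with an estimated correlation. Of 12 interferon response genes 5 rose, among them the isopeptidase Usp18 (1.34 ± 0.25), Oasl2 (1.09 ± 0.12) and the transcription factor Irf7 (0.81 ± 0.10). The count was 8 when adjusted over the list alone (median 0.59; camera adjusted p = 2.41e-07; adjusted p = 0.0563 with an estimated correlation). The cell death list had 7 of 17 higher, with the necroptosis effector Mlkl up by 1.51 ± 0.14 and Casp12 by 1.46 ± 0.25 (8 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.000145; adjusted p = 0.0889 with an estimated correlation). Among 18 NF-κB targets the adhesion molecules Vcam1 (2.30 ± 0.23) and Icam1 (0.49 ± 0.09) and the chemokine Ccl5 (1.10 ± 0.24) rose. The superoxide dismutase Sod2 fell by 0.30 on the log2 scale (6 and 1 when adjusted over the list alone; camera adjusted p = 0.000568; adjusted p = 0.0889 with an estimated correlation). Of 14 oncofetal and tumour markers 7 rose, including Ly6d, Akr1c18, the desaturase Scd2 (2.24 ± 0.38) and the Golgi protein Golm1 (1.66 ± 0.18). There were 9 when adjusted over the list alone (camera adjusted p = 5.62e-07; adjusted p = 0.0708 with an estimated correlation). Nrf2 targets had 3 of 13 higher, Gstm3 (1.02 ± 0.17), Srxn1 (0.81 ± 0.13) and Nqo1 (0.75 ± 0.15), and 8 when adjusted over the list alone (camera adjusted p = 0.000325; adjusted p = 0.119 with an estimated correlation).

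In the bile acid synthesis list 4 of 12 genes fell and none rose, Cyp7b1 most. Acox2 was at -0.38 ± 0.07, Baat, which conjugates bile acids, at -0.35 ± 0.08 and Slc27a5 at -0.28 ± 0.07 (5 lower and 1 higher when adjusted over the list alone; median -0.26; camera adjusted p = 0.00128; adjusted p = 0.0825 with an estimated correlation). The rate-limiting enzyme Cyp7a1 was at 0.91 ± 0.28 and did not pass (adjusted p = 0.0875). Bile acid transporters did not pass as a list (camera adjusted p = 0.817). The uptake carrier Slco1a1 (-1.35 ± 0.17) and the bile salt export pump Abcb11 (-0.29 ± 0.07) were lower and the exporters Abcb1a (0.86 ± 0.19) and Abcb4 (0.67 ± 0.11) higher (4 and 4 when adjusted over the list alone). Cytochrome P450 and conjugation genes had 6 of 18 lower, among them Cyp2c54 (-0.87 ± 0.19), and 9 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.0349; adjusted p = 0.402 with an estimated correlation). The lipid storage list had 3 of 19 higher, also when adjusted over the list alone: the fatty acid transporter Cd36 (2.001 ± 0.10), the lipid droplet protein Cidec (1.71 ± 0.29) and the nuclear receptor Pparg (0.83 ± 0.13; camera adjusted p = 0.0347; adjusted p = 0.382 with an estimated correlation). Cholesterol synthesis genes passed downward with no member called, alone or over all probe sets (camera adjusted p = 0.00649; adjusted p = 0.447 with an estimated correlation). Hepatocyte function (2 of 18 lower, Glul by -0.33 ± 0.07 and Hal by -0.30 ± 0.08) and fatty acid oxidation (2 of 15 higher, Vnn1 and Cpt1a) did not pass, with the same counts when adjusted over the list alone.

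The weaker list calls depended on single arrays. The cytochrome P450 call ended without wild type replicate 1 or 3, NEMO knockout replicate 2 or labelled double knockout replicate 2 (highest adjusted p = 0.103) and under quantile normalisation or median centring (0.0899 and 0.0815). The lipid storage call ended without wild type replicate 1 or 3 or NEMO knockout replicate 3 (highest 0.223) and under cyclic loess (0.0782), and the cholesterol synthesis call without wild type replicate 1 or NEMO knockout replicate 1 (highest 0.114). Fatty acid oxidation passed without NEMO knockout replicate 3 (lowest 0.00984), circadian clock genes without NEMO knockout replicate 2 (0.0251) and under median centring (0.0413), B cell and exocrine pancreas markers without NEMO knockout replicate 1 (0.0395 and 0.0169). Further list members named by the rule are Mcm2 (0.50 ± 0.12), Rbl1 (0.75 ± 0.17), Cdk6 (0.33 ± 0.08), Tnfrsf12a (0.72 ± 0.17), Bcl2l11 (0.68 ± 0.12), Ifit2 (0.77 ± 0.14), Muc1 (0.90 ± 0.21), Prom1 (0.72 ± 0.14), Dcn (0.69 ± 0.08), Cyp2c29 (-0.50 ± 0.10) and Cyp2c50 (-0.50 ± 0.12). Of the 103 genes the rule names here besides the targeted ones, 32 lost their calls without at least 1 array: Hsph1, Rrm2, Mcm6, Mcm10, Btg2, Ccl5, Sod2, Baat, Slc27a5, Abcb1a, Abcb11, Cyp2c54, Glul, Hal, Vnn1, Cpt1a, Nqo1, Epcam, Retnlg, Cd3g, Nkg7, Mcm2, Rbl1, Cdk6, Tnfrsf12a, Cyp2c29, Cyp2c50, Muc1, Prom1, Fmo2, Marco and Dnajb9. The highest adjusted p was 0.155, that of Btg2.

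**Figure D2:**
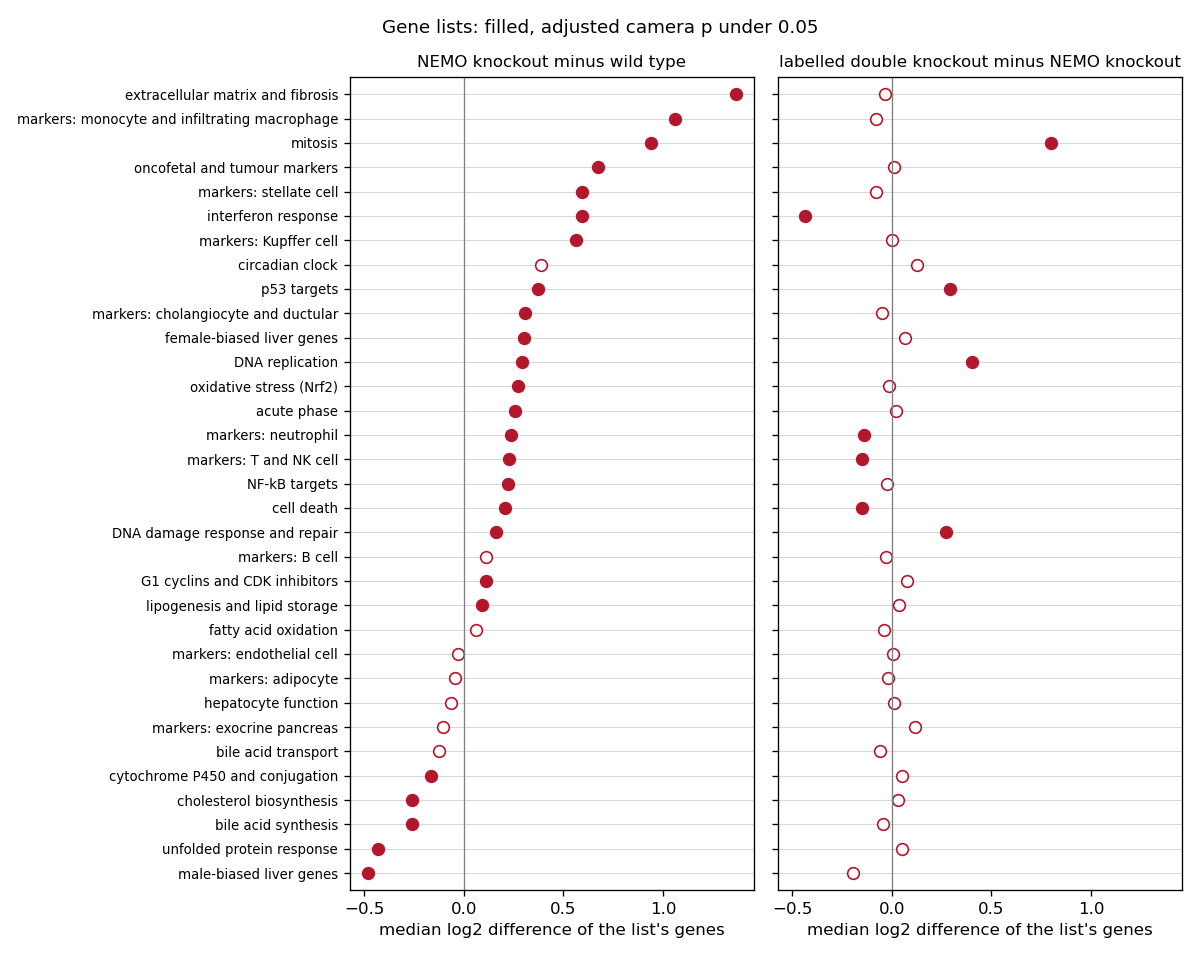
Median log2 difference of each gene list's members (horizontal axis) for the 33 lists tested (rows), NEMO knockout minus wild type on the left and labelled double knockout minus NEMO knockout on the right; filled points passed camera at the preset correlation. Extracellular matrix genes lead on the left with a median of 1.37 and lie at -0.04 on the right, where mitosis genes lead with 0.80.

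Relative to the NEMO knockout, the labelled double knockout had the mitosis and DNA replication lists passing upward, with 1 of 26 and 2 of 25 genes called higher, and the interferon list passing downward, with none of 12 called. These list calls were lost at adjusted p = 0.148, 0.139 and 0.062 with an estimated correlation. Rrm2 rose by 1.65 ± 0.23 (3.14-fold, adjusted p = 0.0348), the spindle protein Prc1 by 1.16 ± 0.15 (2.24-fold, adjusted p = 0.0348) and cyclin E2, Ccne2, by 0.85 ± 0.10 (1.80-fold, adjusted p = 0.0284). These 3 calls depended on nearly every array: with 1 left out Rrm2 kept its call only without NEMO knockout replicate 2, Prc1 only without wild type replicate 1 and Ccne2 only without wild type replicate 1 or 3 (highest adjusted p = 0.161, 0.161 and 0.129). The chloride channel regulator family member Clca3a1 fell by 2.72 on the log2 scale (6.61-fold, SE 0.13, adjusted p = 0.000137), Nipal2 by 2.06 (SE 0.22) and the beta-defensin Defb1 by 1.40 (SE 0.14). Clca3a1 kept its call in all 9 fits with 1 array left out. Nipal2 lost it without NEMO knockout replicate 2 or labelled double knockout replicate 1 (highest adjusted p = 0.0539) and with 2 groups in the fit (0.0708), and Defb1 without NEMO knockout replicate 3 (0.0597). These directions rest on the label, since the Cdkn1a probe set was not lower. In total 57 probe sets were called, 25 higher and 32 lower; 17 of the 57 carried Rps2, a ribosomal protein gene, in their annotation. All 17 were lower, and the others were 25 higher and 15 lower. At an unadjusted p under 0.05 there were 2158, against 1447 by chance.

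The other increases that the rule names were in the interferon-inducible Ifi213 (1.26 ± 0.19), the histone genes H2ac4 (1.14 ± 0.15) and H2bc3 (0.86 ± 0.11) and the phosphatase Acp1 (1.11 ± 0.09). To these add the matrix protein Postn (1.04 ± 0.09), the lipid transporter Abca3 (0.98 ± 0.09), Slc22a26 (0.96 ± 0.14) and Tmem260 (0.89 ± 0.10). The other decreases were in Clca3a2 (-1.40 ± 0.15), Tedc2 (-1.10 ± 0.16), the collectin Colec11 (-1.08 ± 0.11), Akap6 (-0.94 ± 0.08), Rab2b (-0.84 ± 0.08), Sntg2 (-0.83 ± 0.12) and the single-symbol Rps2 probe set (-0.70 ± 0.10). Their adjusted p-values ran up to 0.0446, that of Ifi213. With 1 array left out Acp1, Postn, Abca3, Akap6 and Rab2b kept their calls in all 9 fits, whereas Ifi213, H2bc3, Slc22a26, Tedc2, Sntg2 and Rps2 lost theirs in 8, H2ac4 in 6, Tmem260 in 4, Clca3a2 in 2 and Colec11 in 1 (highest adjusted p = 0.221, that of Ifi213). Abca3, Tedc2 and Rps2 lie within 10 Mb of Cdkn1a in the gene table of assembly GRCm38.p6. The number of calls and the share of them called higher rested on single arrays, while none of the named genes turned its sign. Wild type arrays enter this comparison only through the shared residual spread, so leaving them out changes the p-values and not the differences. Without wild type replicate 1 there were 44, with 36 higher and 8 lower, or 81.8% higher against 43.9%. There were 19 and 14 without wild type replicate 2 or 3, 17, 18 and 11 without NEMO knockout replicate 1, 2 or 3, and 17, 27 and 10 without labelled double knockout replicate 1, 2 or 3. Median centring gave 17 higher and 14 lower, or 54.8% higher.

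Of the 33 lists 8 passed camera, 4 upward and 4 downward, and p53 targets alone held with an estimated correlation. Mitosis genes had a median of 0.80 with 1 of 26, Prc1, called over all probe sets and 23 when adjusted over the list alone, all higher (camera adjusted p = 4.32e-31; adjusted p = 0.148 with an estimated correlation). Cdk1 was at 1.06 ± 0.22 and Top2a at 0.99 ± 0.20, neither past the threshold over all probe sets. DNA replication genes had a median of 0.40, with Rrm2 and Ccne2 called out of 25 and 15 higher when adjusted over the list alone (camera adjusted p = 6.44e-23; adjusted p = 0.139 with an estimated correlation). Among 23 p53 targets Eda2r (0.72 ± 0.10) and Gtse1 (0.66 ± 0.09) rose, and 11 when adjusted over the list alone (median 0.29; camera adjusted p = 6.61e-14; adjusted p = 0.0304 with an estimated correlation). Gtse1 is a microtubule-binding protein of dividing cells as well. With 1 array left out Eda2r lost its call in all 9 fits and Gtse1 in all but that without labelled double knockout replicate 1 (highest adjusted p = 0.167 for both). The DNA damage response list had a median of 0.27 and no member called over all probe sets, with 10 of 23 higher when adjusted over the list alone (camera adjusted p = 6.87e-11; adjusted p = 0.139 with an estimated correlation). The 4 list calls, unlike those of their single genes, were made in each of the 9 fits with 1 array left out.

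Interferon response genes passed downward with a median of -0.44, none of 12 called over all probe sets and 5 lower when adjusted over the list alone (camera adjusted p = 2.71e-09; adjusted p = 0.062 with an estimated correlation). Irf7 stood at -0.42 ± 0.10 and Cxcl9 at -0.74 ± 0.29, neither past the threshold. The lists for cell death (median -0.15, 2 of 17 lower when adjusted over the list alone, camera adjusted p = 0.00365), neutrophils (median -0.14, 2 of 12 lower when adjusted over the list alone, 0.00853) and T and NK cells (median -0.15, 4 of 13 lower when adjusted over the list alone, 0.00952) also passed downward with no member called over all probe sets. Their calls were lost at adjusted p = 0.302, 0.421 and 0.421 with an estimated correlation, and those of the neutrophil and T and NK cell lists also without NEMO knockout replicate 3 or labelled double knockout replicate 2 (highest 0.499 and 0.197). Stellate cell markers had 1 of 12 lower, Colec11, and 1 higher and 1 lower when adjusted over the list alone, and did not pass (camera adjusted p = 0.111). Neither did extracellular matrix genes (median -0.04, camera adjusted p = 0.212), monocyte and macrophage markers (median -0.08, 0.374), NF-κB targets (median -0.02, 0.0882) or bile acid synthesis genes (median -0.04, 0.382), and none of their members was called over all probe sets. With 1 array left out some of these passed: extracellular matrix without NEMO knockout replicate 1 (adjusted p = 0.0185), stellate cells without NEMO knockout replicate 2 (0.0329), and NF-κB targets without NEMO knockout replicate 1 or 2 or labelled double knockout replicate 3 (lowest 0.0217). So did lists not discussed here: exocrine pancreas without wild type replicate 1 or NEMO knockout replicate 1 (lowest 0.00136), male-biased genes without NEMO knockout replicate 1 or labelled double knockout replicate 1 (0.00383), and fatty acid oxidation without NEMO knockout replicate 3 or labelled double knockout replicate 1 (0.00365). Female-biased genes passed without wild type replicate 1, NEMO knockout replicate 1 or labelled double knockout replicate 1 or 2 (lowest 0.0137), and under median centring (0.0484), as did exocrine pancreas (0.0339). Without NEMO knockout replicate 2 bile acid transport, acute phase and Kupffer cells passed (0.0329, 0.045 and 0.0188), without replicate 3 lipid storage and the clock (0.0312 and 0.0337), and without labelled double knockout replicate 2 cytochrome P450 and cholesterol synthesis (0.0373 and 0.0454).

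**Figure D3:**
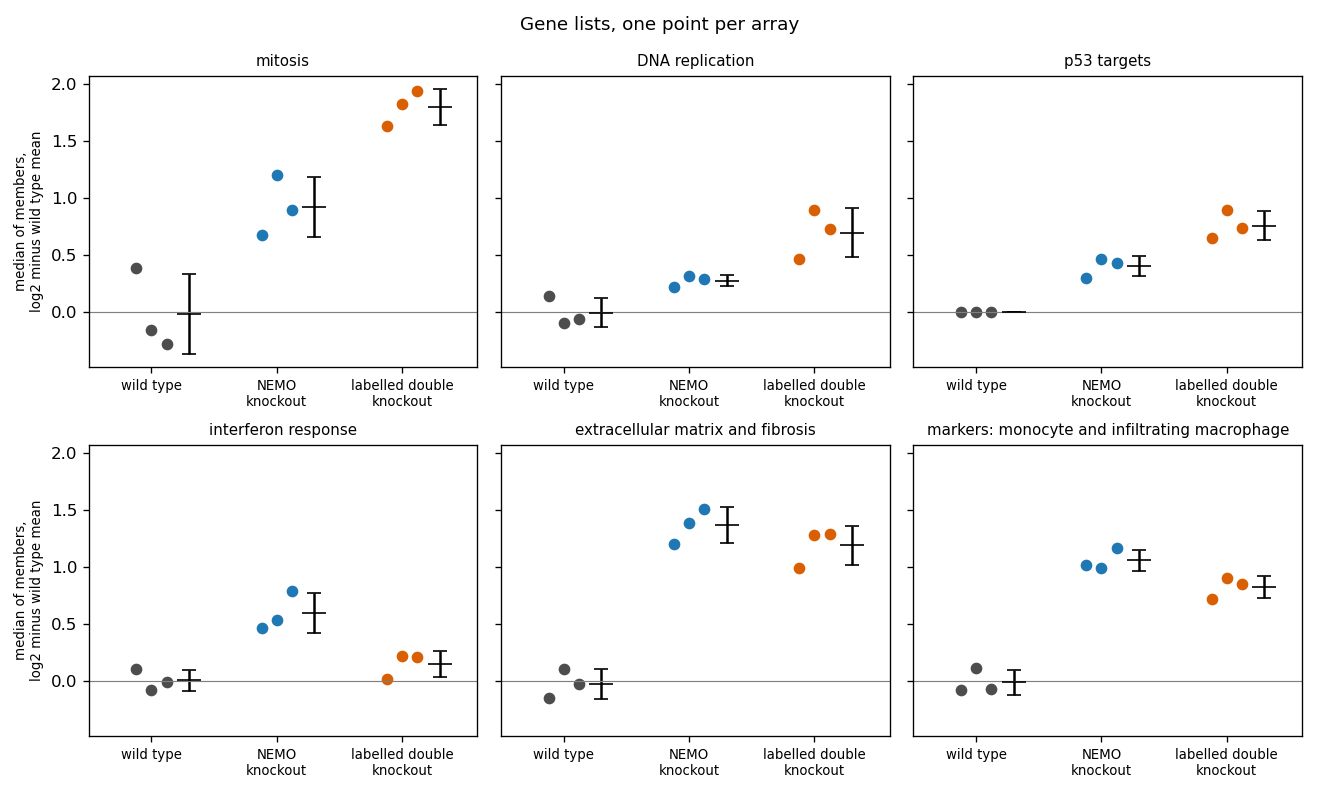
Median over the members of 6 gene lists of the log2 value minus the wild type mean (vertical axis), 1 point per array in wild type, NEMO knockout and labelled double knockout, with the mean and SD of the 3 points as a bar. Mitosis medians were 0.67 to 1.20 in the NEMO knockout and 1.63 to 1.94 in the labelled double knockout, and interferon medians 0.47 to 0.79 and 0.03 to 0.23; the wild type p53 points lie at 0 because the middle member had 1 repeated value there.

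Against wild type, the labelled double knockout had many of the changes of the NEMO knockout but not all of them. Gpnmb (3.96 ± 0.15, 15.6-fold), D17H6S56E-5 (3.81 ± 0.37), Mybl1 (3.71 ± 0.33), Mmp12 (3.67 ± 0.28) and the metallothionein Mt2 (3.33 ± 0.20) had the largest increases. Hsd3b5 (-4.76 ± 0.51, 27.1-fold), Adgrf1 (-3.55 ± 0.27), Elovl3 (-2.58 ± 0.39), Mup21 (-1.85 ± 0.31) and Clca3a1 (-1.84 ± 0.13) had the largest decreases, all 10 with adjusted p at or below 0.00566. Of the 10 largest increases and 10 largest decreases named by the rule in the NEMO knockout, 4 were not called here: Ly6d at 1.98 ± 0.64 (adjusted p = 0.0997), Nipal2 at 0.47 ± 0.22 (0.261), Serpina4-ps1 at -1.58 ± 0.55 (0.126) and Hsph1 at -0.75 ± 0.38 (0.312). Between the knockouts Nipal2 alone of these was called (limma adjusted p = 0.0108). Ly6d (0.254), Serpina4-ps1 (0.616) and Hsph1 (0.698) were not, so a difference between the knockouts is not shown for them. The SD of Ly6d was 1.61 in the labelled double knockout and 0.18 in the NEMO knockout. Clca3a1 and Defb1 (-0.85 ± 0.14), raised there, were below wild type here. There were 2696 calls, 1680 higher and 1016 lower, and 1601 without labelled double knockout replicate 3. Median centring gave 1309 higher and 1661 lower, or 44.1% higher against 62.3%.

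In this comparison 22 of 33 lists passed, 18 upward and 4 downward, and extracellular matrix, monocyte and macrophage, and p53 lists held with an estimated correlation (adjusted p = 0.033, 0.0447 and 0.0187). Of 26 mitosis genes 25 rose (26 when adjusted over the list alone; median 1.81; camera adjusted p = 4.7e-33; adjusted p = 0.0671 with an estimated correlation). DNA replication genes had 21 of 25 higher, and 23 higher and 1 lower when adjusted over the list alone (median 0.64; camera adjusted p = 8.06e-19; adjusted p = 0.0768 with an estimated correlation). DNA damage genes had 12 of 23 higher, and 13 when adjusted over the list alone (camera adjusted p = 6.08e-10; adjusted p = 0.0671 with an estimated correlation). Of the bile acid synthesis list 7 of 12 fell, and 7 lower and 1 higher when adjusted over the list alone, with Cyp7b1 at -1.83 and Abcb11, from the transport list, at -0.49 (camera adjusted p = 0.000635; adjusted p = 0.0671 with an estimated correlation). Interferon genes had 3 of 12 higher, and 4 when adjusted over the list alone (median 0.15; camera adjusted p = 0.0429; adjusted p = 0.255 with an estimated correlation). That call ended without wild type replicate 2 or labelled double knockout replicate 2 or 3 (highest 0.159) and under quantile or cyclic loess normalisation (0.0524 and 0.0609). T and NK cell markers did not pass and none was called (camera adjusted p = 0.14), although they passed without labelled double knockout replicate 2 (0.0291). Lists for NF-κB targets (0.0609), neutrophils (0.0781) and cytochrome P450 genes (0.107), which had passed in the NEMO knockout, did not pass here. They did so without wild type replicate 1 or labelled double knockout replicate 2 (lowest 0.0432), NEMO knockout replicate 3 (0.0203) and labelled double knockout replicate 1 (0.0225), respectively. The lipid storage list ended without wild type replicate 3 or labelled double knockout replicate 3 (highest 0.0922) and cholesterol synthesis without replicate 1 of either group (0.108).

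The 2 comparisons with wild type shared 1231 probe sets called higher and 436 called lower, and 3 were called in opposite directions. Independent lists of these sizes would share 95.1 and 20.5. In the simulations all arrays were redrawn without any change, with the wild type arrays in common, and at most 1 call was shared. Without true change few calls can arise, so that number does not measure what shared arrays add to real calls. Differences correlated at r = 0.841 across probe sets (simulated 0.501), with a covariance of 0.0757 (simulated 0.00687). The simulated covariance is the part that the noise of shared arrays gives in this model. Part of the excess in shared calls may come from the shared wild type arrays, which are too few to be split. Without wild type replicate 3 or labelled double knockout replicate 3, 1101 and 1089 probe sets were shared in direction. Between the NEMO knockout comparison and that of the labelled double with the NEMO knockout, 7 probe sets were called higher in both, none lower in both and 7 in opposite directions. Those higher in both included Rrm2, Prc1, Eda2r and Gtse1, and those that rose in the NEMO knockout and were lower in the labelled double knockout included Clca3a1, Nipal2, Defb1 and Akap6. Independent lists would share 1.42 higher, 0.65 lower and 2.32 opposite, and the shared NEMO knockout arrays alone give r = -0.498 in simulations against -0.178 observed (covariance -0.00882, simulated -0.00682). Without wild type replicates 1, 2 and 3 in turn the number in the same direction was 21, 2 and 0, without those of the NEMO knockout 1, 1 and 0, and without those of the labelled double knockout 2, 3 and 0. In opposite directions it ran from 3 to 7, with 3 without wild type replicate 3, NEMO knockout replicate 3 or labelled double knockout replicate 1 or 3, and 4 without wild type replicate 1.

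Genes near Cdkn1a were tested because a knockout made in cells of another strain can keep neighbouring DNA of that strain. Each gene was represented by its probe set with the highest mean. Between the labelled double and the NEMO knockout, 3 of 503 genes within 10 Mb were called, Abca3, Tedc2 and Pgap6, against 28 of 19353 elsewhere (odds ratio 4.14, 95% interval 0.803 to 13.5, Fisher's exact p = 0.043, 2-sided). Rps2 is not among the 3, because its brightest probe set was not called (-0.30, adjusted p = 0.0952). Counting a gene if any of its probe sets was called, a choice made after seeing the data, gave 4 with Rps2 against 29 elsewhere (odds ratio 5.34, 95% interval 1.36 to 15.3, exact p = 0.00931; 0.000765 within 5 Mb and 0.0247 within 20 Mb), and with 1 array left out this p was under 0.05 in 1 of 9 fits, without labelled double knockout replicate 1 (0.0477). For the brightest probe sets the p was 0.00691 within 5 Mb and 0.0868 within 20 Mb. It passed the threshold in none of the 9 fits with 1 array left out, where 1 or 2 of the nearby genes were called. Against wild type the NEMO knockout had 56 of 503 nearby genes called (p = 0.161 by the same exact test) and the labelled double knockout 68 of 503 (p = 0.0833, and 0.00319 within 5 Mb, where 43 of 251 were called).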

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

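The tests of swapped arrays, of the disrupted allele, of the second annotated gene, of calls lying close together, of any probe set of a gene, of the control block and of other cell types were chosen only after the result was seen, as were the use of the test near Cdkn1a for DNA from another strain in place of the count of close calls and its bar of p under 0.05 at 5, 10 and 20 Mb, while that test itself was fixed earlier and the other tests were written down before their values were seen.

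The Cdkn1a probe set read 0.68 higher, not lower, in the labelled double knockout than in the NEMO knockout. If the arrays of the 2 knockout groups had been swapped and the signal went with p21, the arrays labelled NEMO knockout should read at or below wild type, but they read 1.43 above it. A hypothesis is that RNA of the disrupted allele is still read and follows other p53 targets, whose median was 0.29 higher in the labelled double knockout. That list holds genes of dividing cells, such as Ckap2 and Gtse1, and the mitosis list rose as well (median 0.80), so its rise is not specific to p53. A swap in which the deleted allele keeps its signal could give the same values. The signal may also come from 4930567H12Rik, for which there were 0 other probe sets, so that these cannot be told apart.

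Of the 24 genes called between the 2 knockout groups that entered this count, 11 lay within 5 Mb of another one, against a median of 2 and a 95th percentile of 6 in random sets (permutation p = 0.0017 over 10000 sets). Grouped by chromosome, they were Colec11, Sntg2, G2e3 and Akap6, then Tmem260, Arhgef40, Rab2b and Cebpe, then Abca3, Tedc2 and Pgap6. With the left-out list members, histone genes and close pairs counted too it was 18 of 31. However, with 1 array left out the count passed in none of 9 fits (lowest p = 0.069 by permutation, without NEMO knockout replicate 1). A hypothesis is that DNA of another strain came along with the p21 knockout, but the odds ratio near Cdkn1a, 4.14, had an interval from 0.803 to 13.5 and an exact p = 0.0868 within 20 Mb. With any probe set of a gene it was 5.34 and passed at all 3 windows. Leaving out 1 array ended these calls in 9 and 8 of 9 fits, respectively. The other genes with a close neighbour lie on other chromosomes, so the test leaves this hypothesis open. Neighbours regulated together in damaged liver should cluster in the NEMO knockout too, where as many top genes gave 2. A general fall of ribosomal protein RNA would lower the other ribosomal protein genes along with Rps2, whose 20 probe sets had a median of -0.38, but those had a median of 0.04 (0.0431).

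Mitosis genes had a median 0.80 higher in the labelled double knockout than in the NEMO knockout. A single array should carry it if that were the cause, but the lowest median with 1 of the 6 arrays left out was 0.67. More leukocytes or stromal cells should raise their markers, and the highest median of 7 marker lists was 0.004. Single members spread more widely, from -0.256 to 0.767 for Kupffer cells and from -0.139 to 0.682 for endothelial cells. Such medians also do not show in which cells of the liver the mitosis genes rose. The 3 other normalisations gave at least 0.79, but they moved the median of all probe sets between these groups by at most 0.0048, so they hardly test scaling. In the deposited values the median difference of all probe sets was 0.0033, while the 26 mitosis genes lay at 0.263 to 1.161. A common offset left in these values therefore does not make up the mitosis difference. RMA's quantile step holds that median near 0, so it cannot test a shift of all RNA before that step. A general fall of all RNA that the quantile step removed would not be seen and cannot be told apart here. That loss of p21, which restrains cyclin-dependent kinases, raises these genes remains a hypothesis, with adjusted p = 0.148 with an estimated correlation, a fry adjusted p of 0.0575 and no group lacking p21 alone.

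Among the 6617 probe sets taken to be controls and left out, 9 were called in the NEMO knockout against wild type, 10 in the labelled double knockout against the NEMO knockout and 31 in the labelled double knockout against wild type, with largest increases of 3.04, 4.40 and 4.45. Each comparison allows 10 splits of its 6 arrays, too few for a share under 0.05; the real ones gave 2222, 57 and 2696 calls and the highest of the others 1, 0 and 2.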

How the results depend on the processing

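The tests with the control block included, with any probe set of a gene near Cdkn1a, with Rps2 or tied probe sets left out and without the first array of both knockout groups, and the count of calls lying close together, were chosen only after the result was seen. Against wild type the NEMO knockout had 1042 calls at adjusted p under 0.01 and 1147 of at least 1.5-fold (2222 otherwise), and the labelled double knockout 1246 and 1237 (2696 otherwise). With 1 array left out these ran from 1382 (without NEMO knockout replicate 3) to 2335 and from 1601 (without labelled double knockout replicate 3) to 2720.

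Between the knockout groups the 57 calls became 31 with median centring, 23 with 2 groups in the fit, 9 at adjusted p under 0.01 and 33 of at least 1.5-fold. They became 31 with 1 probe set per gene, 28 with the control block, 35 without Rps2, 6 without the first arrays, and 10 to 44 with 1 array left out. There were 73 with quantile normalisation, 58 with cyclic loess, 70 with the dim filter, 66 with trend, 75 with trend and robust variances, 78 with weights and 64 without tied probe sets. Replicate numbers were not taken as pairs, since in no comparison did the deviations from the group mean correlate over 0.1 for all 3 equal numbers. They correlated at 0.391, 0.083 and 0.247 between the knockouts, 0.18, 0.006 and 0.021 between NEMO knockout and wild type, and 0.095, -0.116 and -0.036 between labelled double knockout and wild type. Between the knockouts each equal-number value exceeded the highest for unequal numbers (-0.184, 0.068 and 0.115), a hint from the data only. A block for the number gave 18 calls here, against 2318 and 2775 in the comparisons with wild type, and moved the cytochrome P450 list to an adjusted p of 0.0583, exocrine pancreas to 0.042 and interferon against wild type to 0.0517. Replicate 1 had the highest array median of its group in wild type, NEMO knockout and labelled double knockout (6.48, 6.579 and 6.551). It also had the lowest mean of the control block in each (6.125, 6.029 and 6.015). An effect shared by equal numbers is therefore not excluded.

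An estimated inter-gene correlation left 3, 1 and 3 lists in place of 25, 8 and 22, and fry 20, 2 and 21. With 1 array left out the lists passing at the preset correlation numbered 22 to 25, 8 to 13 and 20 to 23, with 13 between the knockout groups without NEMO knockout replicate 1 or 2.

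Ikbkg differed by -0.59 to -0.46 (NEMO knockout against wild type), -0.17 to 0.005 (between knockouts, the sign turning without labelled double knockout replicate 1) and -0.69 to -0.51 (labelled double knockout against wild type) with 1 array left out. The Cdkn1a probe set differed by 1.01 to 1.91, 0.50 to 1.001 and 1.69 to 2.59. It passed in the NEMO knockout with array weights (1.69), and lost its call in the labelled double knockout against wild type with 2 groups in the fit (2.11, adjusted p = 0.0507) and without the first arrays (1.93, adjusted p = 0.0994).

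Calls shared in direction between the NEMO knockout comparison and that between the knockouts (7) became 15 with quantile normalisation, 3 with centring, 13 with the dim filter, 13 with trend and robust variances, 13 with weights, 3 with 2 groups, 1 with the block, 1 without the first arrays, and 0 to 21 with 1 array left out. Opposite calls (7) became 4 with centring, 11 with weights, 2 with 2 groups, 3 without the first arrays, and 3 to 7 with 1 array left out. Against wild type the shared calls ran from 1089 to 1518 with 1 array left out and the opposite ones (3) from 1 to 5, with 1 for 2 groups. Genes called near Cdkn1a (3) became 2 with centring (exact p = 0.131), 1 with 2 groups (0.402), 1 with the block (0.265), 1 without the first arrays (0.143) and 1 to 2 with 1 array left out, and stayed 3 within 20 Mb (0.0868). They became 5 with quantile normalisation (exact p = 0.00402), 4 with cyclic loess (0.00745), 4 with the dim filter (0.0185), 4 with trend (0.0114), 6 with trend and robust variances (0.000706), 4 with weights (0.0249) and 4 with any probe set of a gene (0.00931).

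For the named genes other than the targeted ones, 974 of 1027 calls under other settings and 786 of 927 with 1 array left out stayed in the NEMO knockout against wild type, 179 of 228 and 103 of 207 between the knockouts, and 100 of 100 and 90 of 90 in the labelled double knockout against wild type; none turned its sign.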

Other observations

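The tests in this part were all chosen earlier, none of them only after the result was seen. Of the genes named in it, Il1rn, Crp, Cd5l, Per3 and Sult1e1 were picked after their values were seen. Acute phase genes split in the NEMO knockout: 5 of 18 rose, the metallothioneins Mt2 (2.41 ± 0.20) and Mt1 (1.41 ± 0.15), the siderophore-binding Lcn2 (2.19 ± 0.37) and the interleukin receptor antagonist Il1rn (1.14 ± 0.15) among them. The serum amyloid Saa3 (-1.17 ± 0.15) and Crp (-0.49 ± 0.09) fell. Adjusted over the list alone 8 rose and 3 fell (camera adjusted p = 0.0177; adjusted p = 0.184 with an estimated correlation). Genes of the unfolded protein response passed downward, with the chaperone Dnajb9 (-0.84 ± 0.17) and the transcription factor Atf4 (-0.52 ± 0.07) lower and Atf3 (1.03 ± 0.17) higher out of 14. The counts were 6 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.00205; adjusted p = 0.17 with an estimated correlation). Both lists passed in the labelled double knockout against wild type as well (camera adjusted p = 0.0136 and 0.0128; adjusted p = 0.177 and 0.23 with an estimated correlation). Kupffer cell markers went both ways, with Cd5l (0.90 ± 0.08) and Marco (1.03 ± 0.21) raised and Cd163 lowered. With 1 array left out Marco lost its call without wild type replicate 1 or 3 (highest adjusted p = 0.0718) and Dnajb9 without NEMO knockout replicate 2 or 3 (highest 0.0576). The haem synthesis enzyme Alas2, 1 of only 4 measured erythroid genes, fell by 1.06 on the log2 scale (adjusted p = 0.00898).

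Some liver genes that differ between the sexes were called in these male mice. Of 10 male-biased genes Hsd3b5, Elovl3 and Susd4 (-1.29 ± 0.17) fell in the NEMO knockout, and 4 when adjusted over the list alone (camera adjusted p = 0.000326; adjusted p = 0.0708 with an estimated correlation). Fmo2, a flavin monooxygenase, was the 1 of 11 female-biased genes that rose (0.79 ± 0.19), also when adjusted over the list alone (camera adjusted p = 0.0222; adjusted p = 0.27 with an estimated correlation). That list did not pass without wild type replicate 3 or NEMO knockout replicate 1 (highest adjusted p = 0.179), and Fmo2 lost its call in 6 of 9 fits with 1 array left out (highest 0.134). In the labelled double knockout Fmo2 was 1.68 ± 0.19 and the oestrogen sulfotransferase Sult1e1 1.23 ± 0.26 above wild type, 2 of 11 and 4 when adjusted over the list alone (camera adjusted p = 0.00181; adjusted p = 0.167 with an estimated correlation). The clock genes passed there too, with Per3 up by 1.26 ± 0.33 and 2 of 13 called, and 4 when adjusted over the list alone (camera adjusted p = 0.0239; adjusted p = 0.121 with an estimated correlation), but not without wild type replicate 2 (0.0551) or under cyclic loess (0.0609).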
